A study of Mus musculus with 4 samples.

How the data were processed

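The count values were read counts per gene, taken as deposited and per the file headers, with no normalization. The FPKM values were fragment counts scaled by transcript length and library size, computed by the submitters before they were deposited, per the file headers. The TPM values were transcript shares scaled to a fixed sum, deposited beside them and per the file headers, and had nearly the same sum in each library. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2, SAMtools 1.9 and StringTie 2.1.3b with the mouse build mm10. The notes give these tools no roles and do not say how reads were counted or whether strand was used. Counts of 1 went with FPKM values from 0 to 0.746 over 2822 values, so the counts may be rounded from coverage. RNA had been isolated with RNAiso and libraries made with a stranded poly-A kit.

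The table held 45777 genes by Entrez ID, of which 24491 had 0 counts in all 4 libraries. Positions came from the RefSeq annotation of GRCm38.p6, which held 45679 of the IDs. Total counts ran from 31057950 to 42541641, and mitochondrial protein genes took 4.24 ± 0.413% of counts in 6OHA and 4.11 ± 0.142% in control (SD, n = 2). Replicate libraries of a group were not copies of each other, with a chi-square per degree of freedom of 10.2 in 6OHA and 21.3 in control.

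The 4 libraries formed 2 groups of 2, and libraries of cells given bexarotene were not analysed here. Genes were kept by filterByExpr of edgeR 4.0.16, which left 14634, and scaled by TMM, with factors from 0.990 to 1.01. The test was edgeR's quasi-likelihood test without its legacy mode, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05. Replicate numbers were 1 and 3 in 6OHA and 1 and 2 in control, so no pairing was fitted. Levels are counts-per-million of each library's TMM-scaled count over the tested genes, with the SD over 2 libraries. The limits of 3 counts per library use the total count. Differences are 6OHA minus control on the log2 scale. Groups of genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over lists with at least 5 tested members, of which there were 31 among 34. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera takes its degrees of freedom from the 4 libraries, which leaves it little power whatever the correlation. R 4.3.3, DESeq2 1.42.0 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

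The 34 lists, the test, the alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be added later. The lists covered targets of LXR, PPAR, RAR and VDR, nuclear receptors, thyroid hormone response, lipid pathways, inflammation, interferon, microglial states, engulfment, amyloid and risk genes, stress responses, cell cycle, hypoxia, immediate early genes, organelles and markers of other cell types. The rule named the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 5 CPM and groups that did not overlap, clone names left out. It added the 4 members with the smallest p of each list that passed camera, up to 2 members past the threshold of every other pathway list, a fixed set of receptor, lipid and inflammatory genes, and the 2 most abundant markers of each other cell type. Some genes that the rule or the lists hold are not reported here.

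Alternatives were DESeq2 size factors, upper-quartile scaling, the DESeq2 test, limma-voom, the legacy mode, no filter, a mean of at least 5 CPM, limma on log2 FPKM with 1 or 0.1 added and on log2 TPM with 1 added, stricter thresholds, and leaving out each library. In the last, the lone library of a group was assumed to vary like the other group. Replicate 1 of each group differed from the other library with the GC content of genes, as described below. Leaving out 1 library unbalances this between the groups, so calls gained or lost there may partly follow GC content. A GC term per library and lists without their leading members were added after the data were seen. Transcript GC content and shared 31-base stretches came from GENCODE M21 transcripts, with a GC value for 93.4% of tested genes. In 10 simulated data sets of the same size, the test recovered 55.1% of 1.5-fold, 81.5% of 2-fold and 94.7% of 4-fold changes, and 8.48% of its calls were false. Lists of 25 genes shifted by 0.30 were called in 50 of 50 cases and unchanged lists in 0 of 200. Genes were drawn independently, without a GC trend, and all members of a shifted list moved alike. These runs therefore do not show how camera performs when the genes of a list are correlated.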

Results

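RNA-seq was carried out on MG5 cells, a mouse microglial cell line kept in a mixture of plain medium and medium conditioned by A1 astrocyte-like cells. In 2 libraries the cells had received 6OHA, an agonist of the retinoid X receptor (RXR) known here only by its code name, at 10 µM for 6 h. The other 2 libraries came from untreated cells, and the labels do not say whether these received the solvent. RXR is a nuclear receptor that acts in pairs with partners such as the liver X receptors (LXR), the peroxisome proliferator-activated receptors (PPAR) and the retinoic acid receptors (RAR). The comparison asks which transcripts differ after 6 h with the agonist. Libraries from cells given bexarotene, another RXR agonist, were not analysed here. Total counts were 31057950 in 6OHA replicate 1, 35314782 in 6OHA replicate 3, 42541641 in control replicate 1 and 34406649 in control replicate 2. A gene at 0 counts could therefore lie at up to 0.0966, 0.0850, 0.0705 and 0.0872 counts-per-million (CPM) in these libraries, a limit of 3 counts that covers counting error only. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

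Vegfa, Plin2 and Arg1 were among the 10 largest rises, and Hcar2 and Dkk2 among the 10 largest falls, of genes with at least 5 CPM. Vegfa, which encodes a growth factor for blood vessels, was 6.76-fold higher, at 125 ± 11.7 CPM (SD, n = 2) in 6OHA against 18.5 ± 0.778 CPM in control (log2 fold change 2.76, SE 0.11, adjusted p = 1.02e-06). Plin2, the coat protein of lipid droplets, was 4.31-fold higher, at 1782 ± 0.522 against 413 ± 1.49 CPM (adjusted p = 1.02e-06). Arg1, the arginase of alternatively activated macrophages, was 5.53-fold higher, at 10.7 ± 0.856 against 1.95 ± 0.256 CPM (adjusted p = 9.52e-05). The hydroxycarboxylic acid receptor gene Hcar2 was 3.15-fold lower, at 6.17 ± 0.0963 against 19.5 ± 2.62 CPM (adjusted p = 0.000234). The Wnt inhibitor Dkk2 was 2.74-fold lower, at 18.8 ± 0.179 against 51.5 ± 0.181 CPM (adjusted p = 9.11e-05).

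Of 14634 genes tested with edgeR's quasi-likelihood test, 295 passed a Benjamini-Hochberg adjusted p under 0.05, of which 203 rose and 92 fell. Among them, 69 rose and 17 fell by at least 2-fold. The 6OHA libraries lay on one side of both controls for all 295, an order that chance gives 33.3% of genes and that 38.8% of all tested genes showed. The other named rises had log2 fold changes of 2.34 for Col4a2, a basement membrane collagen, 1.95 for the receptor gene Gpr35, 1.89 for the growth factor gene Hbegf, 1.72 for the clock gene Per2, 1.66 for the protease gene Adamts15, 1.61 for the lectin gene Clec10a and 1.59 for Hivep2. The other named falls were Prr5l at -1.22, Cped1 at -1.04, Zfp658 at -1.02, the interleukin 17 receptor gene Il17ra at -0.99, the potassium channel genes Kcnj2 at -0.99 and Kcna3 at -0.99, and Evi2b at -2.49, besides the ferritin pseudogene Ftl1-ps1. Without 6OHA replicate 1 the adjusted p of Cped1 was 0.0890, and without control replicate 1 it was 0.0521. Zfp658 did not pass on log2(FPKM + 1) (adjusted p = 0.0525) or log2(TPM + 1) values (0.0503).

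Positions are on GRCm38, the assembly that mm10 names. Vegfa (Entrez gene 22339) lies on chromosome 17 from 46016993 to 46032377, Arg1 (11846) on chromosome 10 from 24915207 to 24927470, Plin2 (11520) on chromosome 4 from 86626910 to 86670217, Hcar2 (80885) on chromosome 5 from 123863570 to 123865516 and Dkk2 (56811) on chromosome 3 from 132085266 to 132180304. Evi2b (216984) lies on chromosome 11 from 79513385 to 79523762, inside Evi2, which spans 79513385 to 79530609. Of the distinct 31-base stretches of Evi2b transcripts, 98.6% also occur in Evi2, so the split of reads between these genes is uncertain. Evi2b measured 6.32 ± 2.54 CPM in 6OHA and 34.9 ± 13.6 CPM in control, and the summed counts of Evi2, Evi2a and Evi2b differed by a log2 fold change of 0.12 (SE 0.09, adjusted p = 0.743). Ftl1-ps1 shares 63.5% of its 31-base stretches with the ferritin gene Ftl1 and is uncertain in the same way. It measured 342 ± 17.1 CPM in 6OHA and 684 ± 286 CPM in control, and its log2 fold change was -0.49 without control replicate 2 and -1.37 without control replicate 1. Its call was lost under the DESeq2 test (adjusted p = 0.366), limma-voom (0.0823), no filter (0.272) and FPKM and TPM values (at most 0.175). Of the other called genes of the rule, apart from Acaca, Apoc2, Clec10a and Etv5, at least 5% of 31-base stretches were shared with other genes by Glul (20.4%), Tgm2 (918 of 4601), Cped1 (13.4%), Rrm2 (12.8%), Il1a (10.0%), Lpcat3 (9.10%), Slc25a20 (9.02%), Cdc6 (8.79%), Scd1 (8.18%), Ccnd3 (7.95%), Cxcl2 (7.59%), Hivep2 (7.11%), Ccnd2 (6.95%), Scd2 (6.81%) and Plin2 (5.16%). Of genes named later outside the rule, Rps9 (11.8%), Ch25h (9.51%), Fcgr2b (8.15%), Slco2b1 (7.19%), Cxcl3 (5.46%) and Tnfaip2 (5.02%) did so.

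**Figure D1:**
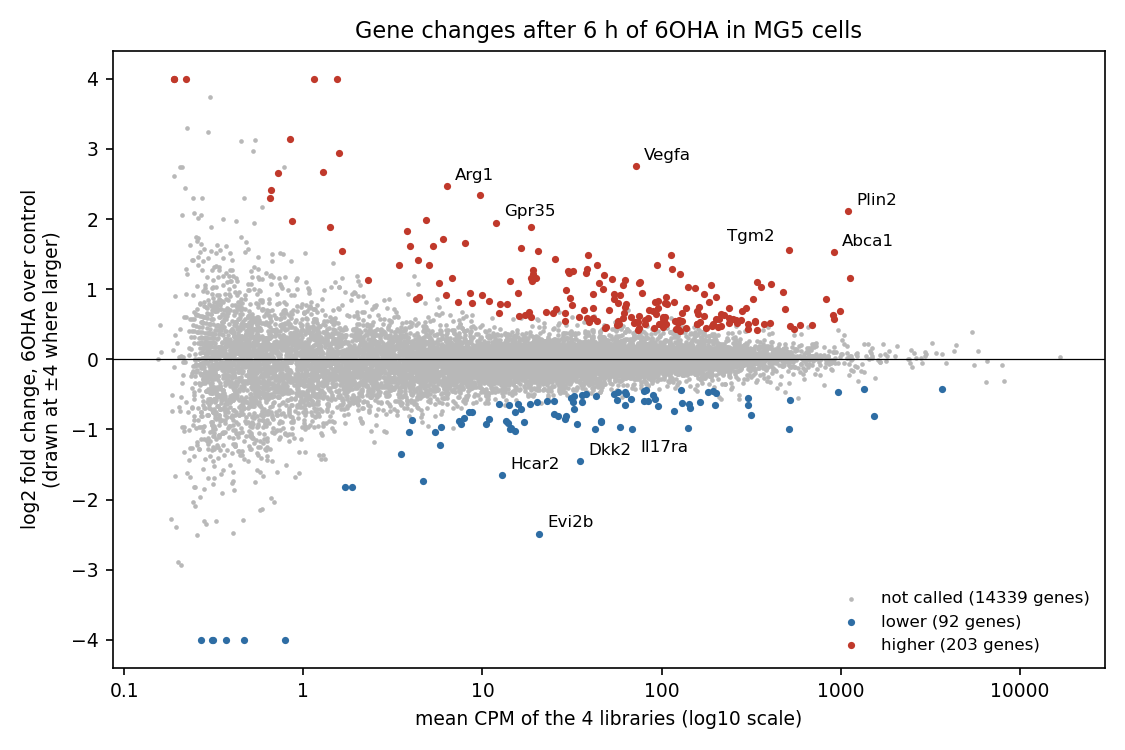
Log2 fold change of 6OHA over control (vertical axis) against the mean CPM of the 4 libraries (horizontal axis, log10 scale) for the 14634 genes tested, with red for the 203 genes that rose, blue for the 92 that fell and grey for the rest. Vegfa and Plin2 stand out among the rises at 2.76 and 2.11, and points beyond 4 in either direction are genes with few counts, drawn at the edge.

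Of 22 measured LXR targets, 8 rose, 0 fell and 14 did not pass. Abca1, which exports cholesterol from the cell, was 2.89-fold higher at 1358 ± 17.0 against 470 ± 58.4 CPM, and its relative Abcg1 was 2.15-fold higher at 467 ± 25.2 against 217 ± 1.86 CPM. Lpcat3, a phospholipid-remodelling enzyme, rose by 0.94 (SE 0.10) on the log2 scale, and Mylip, a ubiquitin ligase gene, by 0.61 (SE 0.10). The call of Mylip was lost with no filter (adjusted p = 0.0726) and on FPKM and TPM values (at most 0.102). Srebf1, the lipogenic transcription factor, and Apoe did not pass, at log2 fold changes of 0.38 (adjusted p = 0.350) and 0.18 (adjusted p = 0.734). Srebf1 measured 152 and 194 CPM in 6OHA replicates 1 and 3, and 113 and 153 CPM in control replicates 1 and 2. It passed without 6OHA replicate 1 and without control replicate 2, where the GC difference between libraries is not balanced between the groups. The median log2 fold change of the LXR list was 0.35 (camera adjusted p = 5.78e-06, and adjusted p = 0.329 with an estimated correlation). Apoc2, an activator of lipoprotein lipase, had a log2 fold change of 1.16, but 78.8% of its 31-base stretches also occur in an overlapping annotated transcript, Gm44805.

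Of 25 measured PPAR targets, 7 rose, 0 fell and 18 did not pass. Besides Plin2 they included the lipid droplet gene Hilpda, 2.68-fold higher at 37.1 ± 0.471 against 13.9 ± 2.00 CPM, and Angptl4, an inhibitor of lipoprotein lipase, 2.16-fold higher at 19.6 ± 0.477 against 9.05 ± 0.407 CPM. Cpt1a, which commits fatty acids to mitochondrial oxidation, was 2.02-fold higher at 206 ± 0.497 against 102 ± 0.303 CPM. The median of the list was 0.16 (camera adjusted p = 1.13e-05, and adjusted p = 0.329 with an estimated correlation). Pdk4, a common PPAR target, had 0 counts in all 4 libraries, as did the RAR target Rarb. Of 10 measured RAR targets, 2 rose and 8 did not pass. Tgm2, a transglutaminase, was 2.95-fold higher at 770 ± 67.3 against 261 ± 18.6 CPM, and Dhrs3, a retinal reductase, rose by 0.52 (SE 0.10). Dhrs3 had an adjusted p of 0.0736 without 6OHA replicate 3 and 0.0591 without control replicate 1. Rara at 0.62 (adjusted p = 0.0864) and Asb2 at 1.54 (adjusted p = 0.399) did not pass. Rara did without 6OHA replicate 1 and without control replicate 2, where GC content is likewise not balanced between the groups. The RAR list had a median of 0.21 (camera adjusted p = 0.0315, and adjusted p = 0.463 with an estimated correlation). With Tgm2 left out its call was lost, at a camera adjusted p of 0.214, while the median of the other 9 genes was 0.17. It was also lost without control replicate 1, at 0.0503, and without control replicate 2, at 0.122. When adjusted over the list alone, 8 LXR targets rose and 1 fell, 10 PPAR targets rose and 1 fell, and 3 RAR targets rose.

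**Figure D2:**
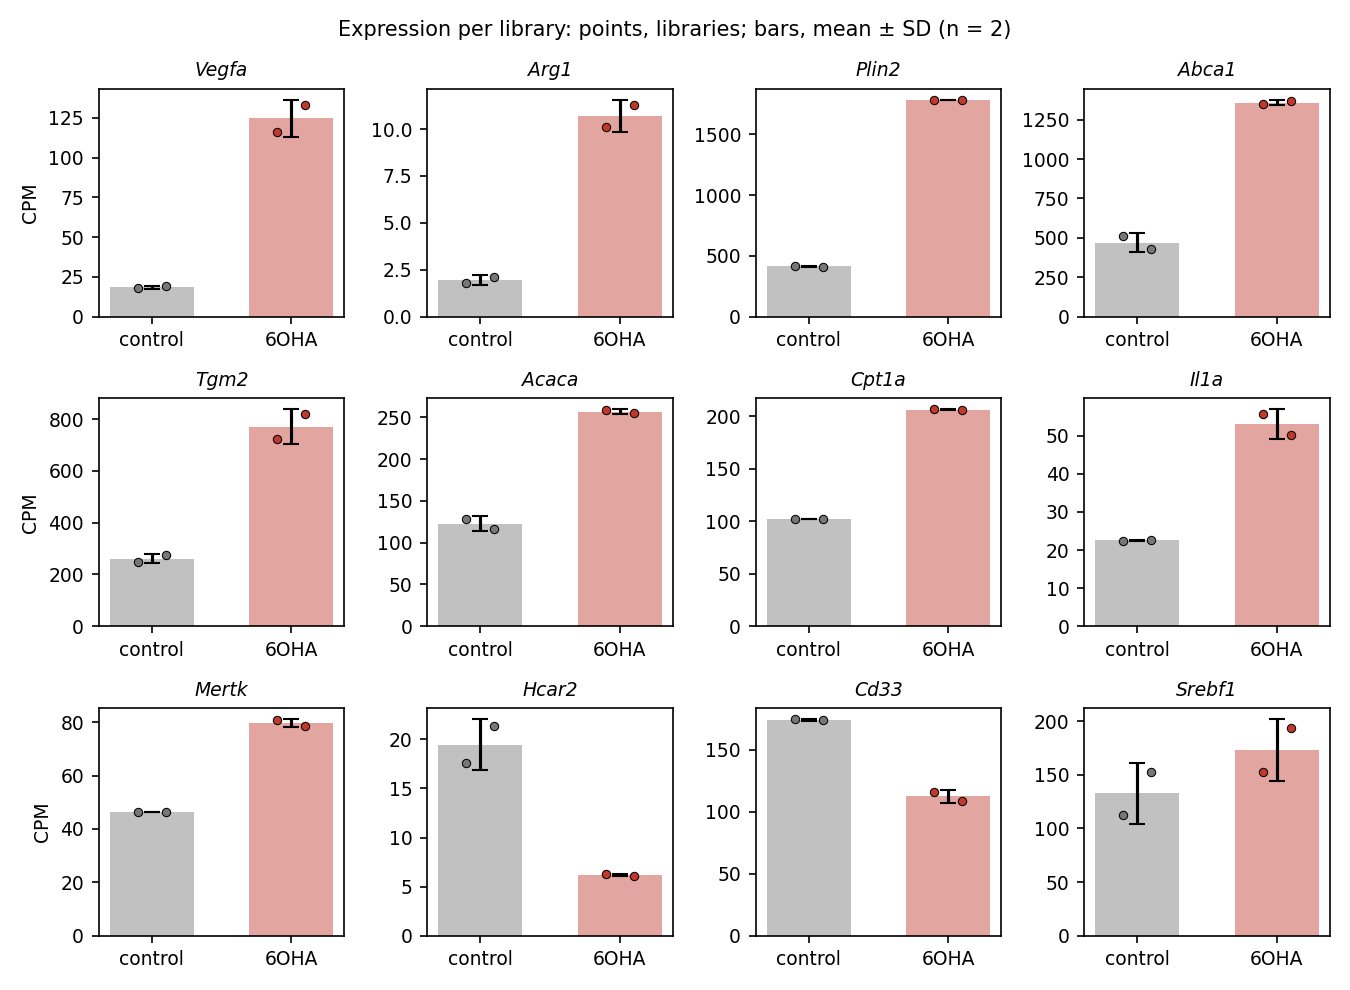
Counts-per-million (vertical axes, from 0) of 12 genes in control (grey) and 6OHA (red) libraries, with a point per library and bars for the mean ± SD of 2 libraries. The libraries of the groups do not overlap for the first 11 genes, while for Srebf1 the higher control library, at 153 CPM, lies above the lower 6OHA library, at 152 CPM.

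Of 19 measured genes of fatty acid synthesis, 4 rose and 0 fell. Acaca, which makes malonyl-CoA, was 2.09-fold higher at 257 ± 2.84 against 123 ± 8.64 CPM, with 31.7% of its 31-base stretches shared with the pseudogene Gm5182. The desaturase genes Scd2 and Scd1 rose by 0.70 (SE 0.09) and 0.65 (SE 0.10), and the phosphatidate phosphatase gene Lpin1 by 0.91 (SE 0.18). The list had a median of 0.17 (camera adjusted p = 1.13e-05, and adjusted p = 0.463 with an estimated correlation). Of 20 genes of triglyceride and lipoprotein handling, 5 rose, namely Plin2, Hilpda, Angptl4, Apoc2 and the lysosomal lipase gene Lipa at 0.52 (SE 0.09), and 0 fell. This list had a median of 0.20 (camera adjusted p = 0.000458, and adjusted p = 0.471 with an estimated correlation). Of 26 genes of fatty acid oxidation, 3 rose and 0 fell, namely Cpt1a, the carnitine carrier gene Slc25a20 at 0.88 (SE 0.11) and Acaa2 at 0.55 (SE 0.10). Abcd2, at 0.43, did not pass (adjusted p = 0.0940) but did without control replicate 1 (0.0254). The list had a median of 0.05 (camera adjusted p = 0.00669, and adjusted p = 0.460 with an estimated correlation). The call of Scd1 was lost with no filter (adjusted p = 0.0560) and on FPKM values (at most 0.0708). Lost calls under left-out libraries were those of Lpin1, with an adjusted p of 0.144 without 6OHA replicate 3, 0.0518 without control replicate 1 and 0.0589 without control replicate 2, and of Acaa2 and Lipa, at 0.146 and 0.0872 without 6OHA replicate 1.

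The cholesterol synthesis list passed camera at the preset correlation with 1 called member. Log2 fold changes were above 0 for 24 of 26 measured genes, with a median of 0.26 (camera adjusted p = 1.46e-07, and adjusted p = 0.329 with an estimated correlation). Only Insig1, a sterol-regulated brake on this pathway, passed over all genes, at 0.45 (SE 0.10), and it did not pass without 6OHA replicate 1 (adjusted p = 0.173), 6OHA replicate 3 (0.197) or control replicate 2 (0.0736). Sc5d at 0.40 (adjusted p = 0.0767, and 0.0372 without control replicate 1), Lss at 0.41 (0.0892) and Hmgcs1 at 0.25 (0.425) did not pass. Adjusted over the list alone, 12 genes of cholesterol synthesis were higher and 0 lower, against 7 of fatty acid synthesis, 5 of fatty acid oxidation and 7 of triglyceride and lipoprotein handling, also with 0 lower.

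Of 35 measured NF-kB and cytokine genes, 6 rose, 0 fell and 29 did not pass. The chemokine gene Cxcl2 was 2.19-fold higher at 85.5 ± 2.60 against 38.9 ± 1.17 CPM, Il1a, which encodes interleukin 1 alpha, was 2.35-fold higher (log2 fold change 1.23, SE 0.11), and the monocyte chemoattractant gene Ccl2 was 1.54-fold higher at 1096 ± 42.9 against 710.0 ± 30.5 CPM. On FPKM and TPM values the call of Ccl2 was lost, at adjusted p values from 0.0508 to 0.0897. Ccl7, Tnfaip2 and Cxcl3, the rest of the risen members, are named here after their values were seen. So are the fallen members of the list of anti-inflammatory and alternative activation genes, called alternative activation below. Cxcl3 had 25 counts in the 6OHA libraries and 0 in the controls, at least 9.84-fold higher against a floor of 3 counts over the group, and shares sequence with Cxcl2. Tnf at -0.18 (adjusted p = 0.604), Il1b at -0.41 (adjusted p = 0.224), Il6 at 0.61 (adjusted p = 0.780) and the nitric oxide synthase gene Nos2 at -0.78 (adjusted p = 0.0594, and 0.0376 without control replicate 1) did not pass. The list did not pass camera (adjusted p = 0.158), and its median was 0.03, also with Cxcl3 at its bound. Among 13 anti-inflammatory and alternative activation genes, Arg1 and Clec10a rose, while Klf4 at -0.78, Socs3 at -0.49 and Il1rn, the interleukin 1 receptor antagonist gene, at -0.47 fell (camera adjusted p = 0.969). With 1 library left out, calls were lost for Ccl7 (without 6OHA replicate 1, adjusted p = 0.0712), Cxcl3 (without control replicate 1, 0.0704), Tnfaip2 (without either 6OHA library or control replicate 1, at most 0.346), Socs3 (without either 6OHA library or control replicate 2, at most 0.320) and Il1rn (without 6OHA replicate 3 or control replicate 1, at most 0.267). Clec10a shares 13.7% of its 31-base stretches with its neighbour Mgl2. Adjusted over the list alone, 8 inflammatory genes were higher and 3 lower, and 3 genes of alternative activation were higher and 3 lower.

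The interferon response list lay below 0 without a called member. Of its 35 measured genes, 30 had log2 fold changes below 0, with a median of -0.13 (camera adjusted p = 0.00342, and adjusted p = 0.671 with an estimated correlation). Ifit1 at -0.54 (adjusted p = 0.0597), Isg15 at -0.38 (0.160) and Cmpk2 at -0.41 (0.210) did not pass, nor did Lgals9 at 0.30 (0.196). Ifit1 did pass under the DESeq2 test and with the filter at a mean of at least 5 CPM. Counted as adjusted over the list alone, 1 gene was lower. The call was lost without 6OHA replicate 3 (camera adjusted p = 0.703), and the median of the list differed by 0.15 between the 6OHA libraries themselves.

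Of 20 homeostatic microglia markers, 2 rose, 1 fell and 17 did not pass. In this list the transporter gene Slco2b1 rose by 0.81 (SE 0.11) and the fractalkine receptor gene Cx3cr1 fell by 0.81 (SE 0.11). Tmem119 at 0.26 (adjusted p = 0.668) and P2ry12 at -0.15 (adjusted p = 0.720) did not pass. Of 30 disease-associated microglia markers, the chemokine gene Ccl6 rose by 1.16 (SE 0.09) and the receptor gene Axl by 0.53 (SE 0.09), and the cholesterol hydroxylase gene Ch25h fell by 0.98 (SE 0.11) and Ank by 0.52 (SE 0.10). Trem2 was at -0.03 (adjusted p = 0.971). Of 20 macrophage identity genes, Irf8 rose by 0.43 (SE 0.09). None of these lists passed camera, with adjusted p values of 0.950, 0.961 and 0.971, while fry's mixed test, which asks whether members change in either direction, passed the homeostatic and disease-associated lists (adjusted p = 0.00543 and 0.00108). Fry does not compare a list with other genes, and its mixed test passed 19 of the 31 lists tested. The called members given here for these 3 lists are named after their values were seen. With 1 library left out, calls were lost for Irf8 (without either 6OHA library or control replicate 1, at most adjusted p = 0.279), Axl (without 6OHA replicate 3, 0.0956) and Ank (without either 6OHA library, at most 0.170). Adjusted over the list alone, 3 homeostatic markers were higher and 3 lower, 4 disease-associated markers were higher and 4 lower, and 1 identity gene was higher.

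Of 38 measured engulfment genes, a list of phagocytosis and clearance of dying cells, 5 rose, 3 fell and 30 did not pass. Mertk, a receptor for dying cells, was 1.72-fold higher at 79.8 ± 1.48 against 46.4 ± 0.00243 CPM. Tgm2, Axl, the scavenger receptor gene Cd36 at 0.49 and Scarb2 at 0.56 also rose, while Tlr2 at -0.70, the integrin gene Itgb3 at -0.86 and the inhibitory Fc receptor gene Fcgr2b at -0.42 fell. These, apart from Tgm2, are named after their values were seen, and calls were lost for Cd36 (without 6OHA replicate 1 or control replicate 2, at most adjusted p = 0.254), Scarb2 (without 6OHA replicate 1, 0.0804), Axl (without 6OHA replicate 3, 0.0956) and Fcgr2b (without either 6OHA library or control replicate 1, at most 0.397). Of 32 amyloid and Alzheimer risk genes, Cd33, a sialic acid receptor, was 1.55-fold lower at 112 ± 5.26 against 174 ± 0.690 CPM, and Picalm, an endocytic adaptor, was 1.39-fold higher at 604 ± 37.2 against 435 ± 27.1 CPM. Picalm did not pass without 6OHA replicate 1 (adjusted p = 0.229) or control replicate 2 (0.0573). Neither list passed camera (adjusted p = 0.532 and 0.704). Both passed fry's mixed test (adjusted p = 0.00314 and 0.00181), which does not compare a list with other genes. When adjusted over the list alone, 6 engulfment genes were higher and 4 lower, and 3 amyloid and risk genes were higher and 1 lower.

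Cell cycle genes lay below 0. Of 40 measured genes, 34 had log2 fold changes below 0, with a median of -0.13 (camera adjusted p = 0.000418, and adjusted p = 0.329 with an estimated correlation). The replication licensing gene Cdc6 fell by 0.55 (SE 0.11), the ribonucleotide reductase gene Rrm2 by 0.58 (SE 0.12) and the D cyclin gene Ccnd3 by 0.67 (SE 0.14), while its relative Ccnd2 rose by 0.55 (SE 0.11). Each of these 4 calls was lost with 1 library left out. The largest adjusted p was 0.181 for Cdc6, 0.0932 for Ccnd3 and 0.266 for Ccnd2 without 6OHA replicate 1, and 0.389 for Rrm2 without 6OHA replicate 3. The others were 0.124 for Cdc6 and 0.0582 for Ccnd2 without 6OHA replicate 3, 0.0719 for Ccnd3 and 0.0502 for Ccnd2 without control replicate 2, and 0.0750 for Rrm2 without control replicate 1. The proliferation marker genes Mki67 at -0.02 and Cdk1 at -0.03, named after their values were seen, did not pass. Adjusted over the list alone, 10 cell cycle genes were lower and 1 higher.

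Of 31 measured genes of glycolysis and hypoxia, only Vegfa and Hilpda rose and 0 fell, and both counts were the same when adjusted over the list alone. Pfkl at 0.39 (adjusted p = 0.183) and Ankrd37 at 0.61 (adjusted p = 0.366) did not pass, and the glucose transporter gene Slc2a1, named after its value was seen, was at -0.00 (adjusted p = 1.00). The list had a median of 0.13 (camera adjusted p = 0.00216, and adjusted p = 0.620 with an estimated correlation), and an adjusted p of 0.0351 with Vegfa and Hilpda left out. Its call was lost without 6OHA replicate 3 (camera adjusted p = 0.0712). The 35 measured genes of the unfolded protein and integrated stress response had 0 called members, also when adjusted over the list alone, and a median of 0.04 (camera adjusted p = 0.0499, and adjusted p = 0.463 with an estimated correlation). Xbp1 at 0.34, Ern1 at 0.39, Ppp1r15a at 0.37 and Slc7a11 at -0.35 had the smallest p-values in it and did not pass, though without control replicate 2 Xbp1 (adjusted p = 0.0484) and Slc7a11 (0.0175) did. The list no longer passed with Ddit4 left out (adjusted p = 0.0960), a gene with 4 counts in the controls, and leaving out any 1 library gave adjusted p values from 0.0549 to 0.247.

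**Figure D3:**
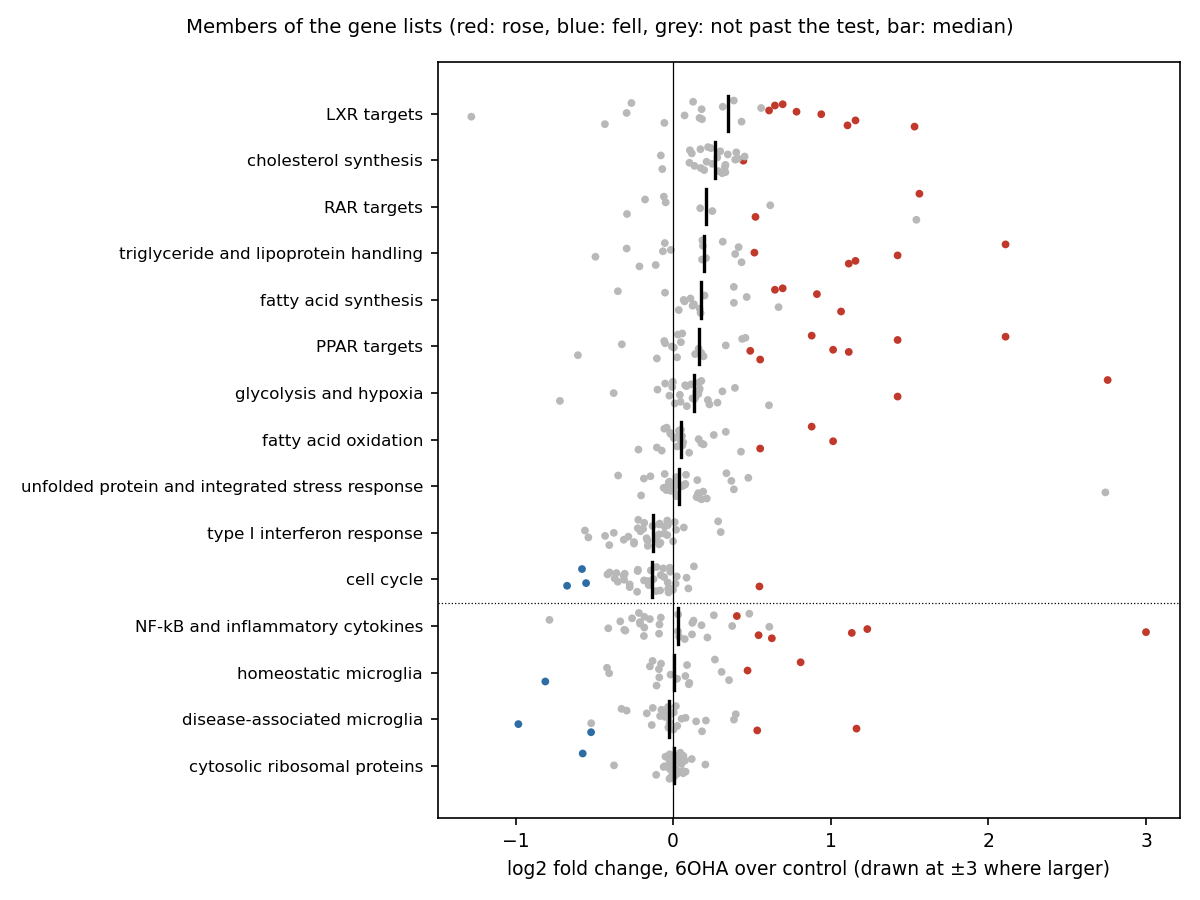
Log2 fold change of 6OHA over control (horizontal axis) for each measured member of the 11 lists that passed camera (above the dotted line) and of 4 that did not (below it), with red for genes that rose, blue for genes that fell, grey for genes that did not pass and a black bar for the median. The LXR list has the highest median, 0.35, and the cell cycle and interferon lists lie lowest, at -0.13 each.

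The remaining lists did not pass camera. Among 32 immediate early genes, 3 rose and 2 fell, and Dusp6 at 0.65 (SE 0.09) and Etv5 at 0.62 (SE 0.09) had the smallest p-values (camera adjusted p = 0.950). The others, named after their values were seen, were Fos at 0.82, Klf4 and Dusp4 at -0.60, and calls were lost for Fos (without 6OHA replicate 3 or either control, at most adjusted p = 0.306) and Dusp4 (without 6OHA replicate 1 or control replicate 1, at most 0.301). Etv5 shares 30.3% of its 31-base stretches with the pseudogene Gm4798, and its call was lost on log2(FPKM + 1) values (adjusted p = 0.0600). Of 40 lysosome and autophagy genes, Lipa rose (camera adjusted p = 0.158). Of 8 VDR targets, Thbd, which encodes thrombomodulin, rose by 1.13 (SE 0.25), with an adjusted p of 0.148 without 6OHA replicate 3 and 0.152 without control replicate 1 (list adjusted p = 0.950). Of 34 ribosomal protein genes, Rps9, named after its value was seen, fell by 0.57 (SE 0.12, list adjusted p = 0.950), with an adjusted p of at most 0.0931 without 6OHA replicate 1 or control replicate 2. None of the 18 nuclear receptor genes, 6 thyroid hormone response genes, 28 NRF2 genes, 18 heat shock genes, 23 p53 targets, 36 respiratory chain genes or 20 antigen presentation genes passed, and the smallest camera adjusted p of these lists was 0.697, for thyroid hormone response. When adjusted over the list alone, the higher and lower counts were 3 and 4 for immediate early genes, 2 and 0 for lysosome genes, 1 and 1 for VDR targets, 0 and 1 for ribosomal proteins, 2 and 0 for nuclear receptors and 1 and 0 for thyroid response. They were 0 and 0 for NRF2, 1 and 0 for heat shock, 2 and 1 for p53 targets, 0 and 1 for the respiratory chain and 1 and 0 for antigen presentation. Median, mean and test differed in sign for the lists of VDR targets, nuclear receptors, thyroid response, alternative activation, heat shock, immediate early genes, antigen presentation and ribosomal proteins.

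Among the receptor genes themselves, Rxra, with 144 ± 15.7 CPM in 6OHA and 156 ± 7.32 in control, did not pass (log2 fold change -0.11, adjusted p = 0.831). Over all libraries Rxrb averaged 32.9 CPM, and Rxrg had 0 counts in each. The LXR gene Nr1h2 averaged 44.6 CPM and the LXR gene Nr1h3 0.508 CPM. Of the PPAR genes, Ppard was at 36.8 ± 3.25 CPM in 6OHA and 39.3 ± 5.22 CPM in control, Ppara had 0 counts in each library and Pparg had 4 counts in each control and 0 in each 6OHA library. Rara averaged 42.2 CPM and Rarg 13.3 CPM.

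Markers of other cell types were low in part. The astrocyte marker Gfap had 0 counts in all 4 libraries, and the most abundant astrocyte markers were Glul and Acsbg1, which macrophages can also express. Glul rose from 102 ± 5.20 to 138 ± 3.79 CPM, with an adjusted p of 0.166 without 6OHA replicate 1, 0.323 without 6OHA replicate 3 and 0.0835 without control replicate 1. Acsbg1 was at 15.3 ± 1.57 and 19.9 ± 0.277 CPM (adjusted p = 0.250). Of the neuron markers, Map2 fell from 10.9 ± 0.369 to 6.47 ± 0.329 CPM, with an adjusted p of 0.140 without 6OHA replicate 1, 0.0638 without 6OHA replicate 3 and 0.0704 without control replicate 1, and Syn1 was at a log2 fold change of 0.57 (SE 0.13, adjusted p = 0.0568, and 0.0310 without control replicate 2) and a mean of 20.5 CPM. Of the oligodendrocyte markers, Mbp was at 78.8 ± 1.86 in control and 97.7 ± 3.04 CPM in 6OHA (adjusted p = 0.170) and Cnp at 22.4 ± 1.92 and 24.5 ± 2.16 CPM (adjusted p = 0.832). Of the fibroblast and endothelial markers, Kdr was at 237 ± 18.0 and 205 ± 1.12 CPM (adjusted p = 0.441) and Vwf at 53.2 ± 0.381 and 54.3 ± 7.54 CPM (adjusted p = 0.971). Of the dendritic cell and lymphocyte markers, Batf3 was at 4.34 ± 1.56 and 4.46 ± 0.937 CPM (adjusted p = 0.970) and Cd4 at 1.12 ± 0.234 and 1.33 ± 0.592 CPM (adjusted p = 0.916). The astrocyte list and the fibroblast and endothelial list did not pass camera, at adjusted p = 0.950 and 0.804, and the other 3 lists had fewer than 5 tested members. Adjusted over the list alone, the higher and lower counts were 2 and 2 for astrocyte, 1 and 2 for neuron, 1 and 1 for oligodendrocyte and 0 and 0 for the fibroblast and endothelial and the dendritic cell and lymphocyte markers.

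Libraries differed with the GC content of genes in both groups alike. Over 10223 genes with at least 5 CPM, the log2 difference between 6OHA replicates 1 and 3 correlated with transcript GC at r = -0.55, that between control replicates 1 and 2 at r = -0.61, and the difference between the groups at r = 0.00. These are correlations across genes, which are not independent replicates. The first principal component held 42.8% of the variance and separated the groups, and the next held 30.7% and separated replicate 1 of each group from the other library. With a GC term per library, chosen after the data were seen, 777 genes passed, 471 higher and 306 lower, among them 294 of the 295 above. In simulated counts with a GC trend per library, the term found 200 of 200 changed genes, against 189 without it. It also called 15 unchanged genes, against 2 without it, so some of the added calls may be false. The simulated changes were all 2-fold rises, with a linear trend and the same dispersion for every gene. The share of false calls among the added genes may therefore differ in the real data. Of the 35 named genes that were tested and had not passed, 22 did with this term, among them Srebf1, Apoe, Hmgcs1, Sc5d, Lss, Nos2, Ifit1 and Isg15. On log2(TPM + 1) values 152 genes passed, 78.9% of them higher against 68.8% of the 295. Without control replicate 2, 143 genes passed as lower.

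**Figure D4:**
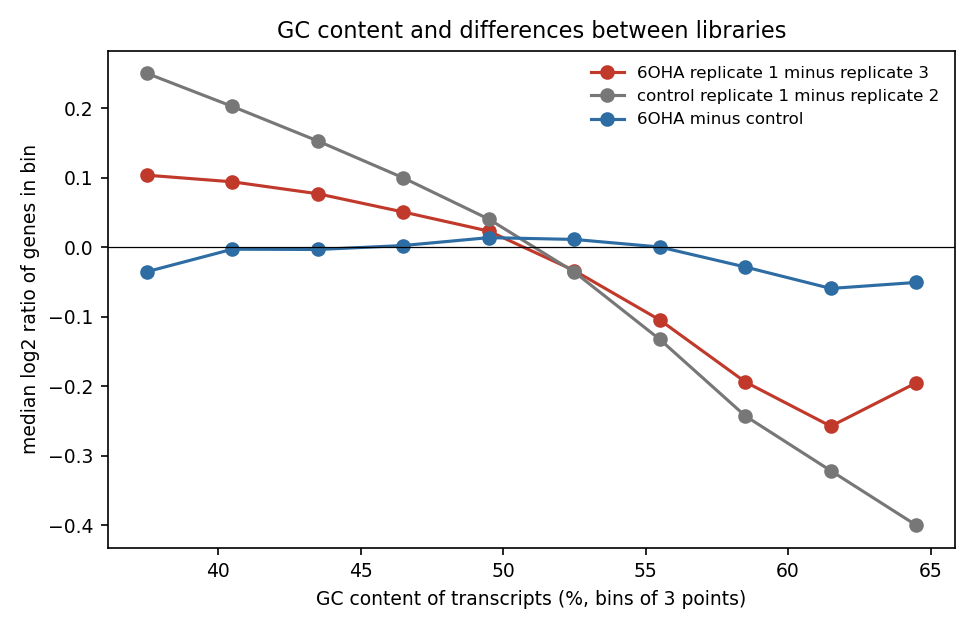
Median log2 ratio of genes (vertical axis) in bins of 3 points of transcript GC content (horizontal axis, %) for the 6OHA libraries against each other, the control libraries against each other, and 6OHA against control. Between the control libraries the median runs from 0.25 in the lowest bin to -0.40 in the highest and between the 6OHA libraries from 0.10 to -0.20, while the difference between the groups stays between -0.06 and 0.01.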

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

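The 295 changed genes kept their direction under each alternative that tested them, 260 of them at a mean of at least 5 CPM and 295 elsewhere. That was all but fixed in advance, since each alternative reuses these libraries and the groups overlapped for none of the 295. The absence of reversals, here and among the named genes below, is therefore no separate support. The count stayed within 1.5 times under DESeq2 size factors (310), upper-quartile scaling (301), the DESeq2 test (430), limma-voom (269), the legacy mode (275) and a mean of at least 5 CPM (302). It fell to 120 with no filter on low counts, 96 higher and 24 lower, where 21286 genes were tested. It was 135 on log2(FPKM + 1), 101 higher and 34 lower, 149 on log2(FPKM + 0.1), 109 higher and 40 lower, and 152 on log2(TPM + 1), 120 higher and 32 lower, and the cause was not tested. The share of higher genes was 68.8%, 78.9% on TPM and 80.0% with no filter. An adjusted p under 0.01 left 149, 118 higher and 31 lower, and a minimum of 2-fold left 86, 69 higher and 17 lower, both by construction. The GC term, chosen after the data were seen, gave 777, 471 higher and 306 lower, with 294 of the 295 among them. In simulated counts, under the simplified settings given above, this term called 15 unchanged genes, against 2 without it. Leaving out each library gave 266 to 397 changed genes, 167 to 254 higher and 77 to 143 lower, with 143 without control replicate 2, and 205 to 262 of the 295 were shared. Each left-out library also unbalances the GC difference between libraries over the groups, so calls gained or lost there may partly follow GC content. No paired analysis was possible because the groups share only replicate number 1. With an estimated correlation the adjusted p was 0.329 for the LXR, PPAR, cholesterol synthesis and cell cycle lists, 0.463 for the RAR, fatty acid synthesis and unfolded protein lists, 0.460 for fatty acid oxidation, 0.471 for triglyceride handling, 0.671 for interferon and 0.620 for hypoxia. Estimated correlations lay below the preset 0.01 for LXR (0.00866), PPAR (-0.0353), RAR (-0.105), fatty acid oxidation (-0.0263), cell cycle (-0.0110) and unfolded protein (-0.00299). For these, correlation between genes cannot account for the larger p-values. The other lists given here lay between 0.0263 and 0.199, and the smallest adjusted p of all 31 lists was 0.329. Fry in one direction gave 0.0577 for LXR and RAR, 0.0736 for cholesterol synthesis, 0.149 for fatty acid synthesis, 0.1501 for triglyceride handling, 0.445 for interferon, 0.208 for unfolded protein and 0.181 for hypoxia, and passed PPAR (0.0255), fatty acid oxidation (0.0238) and cell cycle (0.0238). Fry's mixed test gave 0.407 for interferon and 0.0652 for unfolded protein, but passed 19 lists, 10 of which had not passed camera: immediate early (0.000780), disease-associated (0.00108), NF-kB and amyloid (0.00181), alternative activation and engulfment (0.00314), lysosome (0.00485), homeostatic (0.00543), astrocyte (0.00698) and VDR (0.0282). The RAR list had 0.174 with no filter, 0.0255 to 0.122 with 1 library left out and 0.214 less Tgm2. The unfolded protein list had 0.0603 under upper-quartile scaling, 0.0788 with no filter, 0.107 at 5 CPM, 0.0915 on log2(FPKM + 1), 0.0549 to 0.247 with 1 library left out and 0.0960 less Ddit4. With 1 library left out the interferon list ranged from 9.02e-05 to 0.703 and the hypoxia list from 0.000696 to 0.0712. The settings that left out list members were chosen after the data were seen, and the causes of the lost list calls were otherwise not tested. Of 1314 values of 88 named genes, 1164 were on the same side of the threshold, 108 no longer passed, 42 newly passed, 22 of them with the GC term, and 0 called values reversed. Sign changes occurred in 12 values that did not pass, and 83 of the 88 genes had none. Of 53 called named genes, 39 passed with any 1 library left out. On log2(FPKM + 1) values 20 of the 53 lost their call, namely the 14 lost with some library left out and Ftl1-ps1, Scd1, Zfp658, Mylip, Ccl2 and Etv5. The number lost was 18 on log2(FPKM + 0.1), 16 on log2(TPM + 1), 17 with no filter, 2 each under the DESeq2 test and limma-voom (Ftl1-ps1 and Thbd) and 2 in the legacy mode (Thbd and Glul), and the cause was not tested. Depth limits genes at few counts, since 3 counts correspond to 0.0705 to 0.0966 CPM.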

Other observations

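The tests of GC content, sequencing depth, overlapping gene bodies and the summed Evi2 counts were chosen only after the result was seen. The genes named next lie outside the fixed lists or rule and were also chosen after their values were seen. The inhibitory receptor gene Cd300a was 2.33-fold higher at 178 ± 3.14 against 76.4 ± 2.17 CPM (SD, n = 2) and shares 8.20% of its 31-base stretches with other genes, the complement receptor gene C5ar1 was 1.95-fold higher at 627 ± 35.3 against 322 ± 49.2 CPM and the kinase gene Syk was 1.66-fold higher at 295 ± 7.43 against 178 ± 0.814 CPM. The iron exporter gene Slc40a1 was 2.22-fold higher, the potassium channel gene Kcnj10 2.05-fold higher and St3gal5, which makes the ganglioside GM3, 2.39-fold higher. Among the falls, the intermediate filament gene Vim was 1.76-fold lower at 1117 ± 22.4 against 1963 ± 116 CPM, the growth factor gene Areg 3.34-fold lower and the collagenase gene Mmp13 1.57-fold lower. All of these passed with any 1 library left out. The transporter gene Abcc2 had 0 counts in the 6OHA libraries and 48 in the controls, at least 13.6-fold lower against a floor of 3 counts over the group.

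The tumour suppressor gene Trp53, which encodes p53, averaged 2.30 CPM over the 4 libraries, and Cdkn1a, which p53 can induce, 78.4 CPM. Whether p53 acts in these cells was not tested, so the p53 target list cannot show that a working pathway failed to respond. The macrophage genes Lyz2, Csf1r and C1qb averaged 8002, 2956 and 1039 CPM, while Sall1, a microglial transcription factor gene, had 0 counts in each library.

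Libraries of different groups deviated together. Across 10223 genes, the difference between 6OHA replicates 1 and 3 correlated with that between control replicates 1 and 2 at r = 0.356 (bootstrap 95% interval 0.297 to 0.412, across genes, which are not independent replicates). Sequencing depth would give a correlation below 0, since 6OHA replicate 1 was the shallower library of its group and control replicate 1 the deeper, so the value argues against depth. After a GC term per library the correlation was 0.0119 (-0.0426 to 0.0601), so GC content in library preparation or sequencing may account for it, and no biological explanation was tested. The term was fitted to these same libraries, so the drop shows that the shared part follows GC and is no separate test of the cause. The split of the 4 libraries that follows this axis gave 0 genes with edgeR and 943 at an unadjusted p under 0.05, against 295 and 1591 for the real groups and 1 and 149 for the other split, and 3 splits are too few for a share under 0.05. Splits other than the real one hold libraries of both groups on each side. The difference between the groups then adds to their spread and can lower their counts, so they are no null for the 295.

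Called genes lay near each other more often than random genes did, also among the falls (5 pairs against a median of 1, permutation p = 0.0116, and 3 against 0 among genes sharing under 5% of their 31-base stretches, permutation p = 0.0195). Within 100 kb there were 25 pairs of risen genes, among them Ccl2 with Ccl7, Ccl9 with Ccl6, and Thbd with Cd93, against a median of 6 and a highest count of 20 in 10000 draws matched on expression (permutation p = 1e-04, the smallest they can give). Among risen genes sharing under 5% there were 10 pairs against a median of 3 (permutation p = 0.0017), which argues against shared reads as the whole cause. Without overlapping pairs 8 were left against a median of 3 (permutation p = 0.0123), which argues against overlap of annotated gene bodies as the whole cause. Reads past annotated gene ends were not tested, and Dmwd and Dmpk lay 868 bp apart. Of these 8 pairs, all but Ccl9 with Ccl6 held a gene whose call was lost with some library left out. Other causes, such as shared regulation of neighbours, stay open and were not tested.

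Evi2b had the largest fall among the genes named by the rule, at a log2 fold change of -2.49. It lost 28.6 CPM while Evi2, which contains it, gained 56.3 CPM and Evi2a 5.21 CPM, and their summed counts had a log2 fold change of 0.12 (SE 0.09, adjusted p = 0.743). The fall may therefore come from how reads were assigned between these overlapping genes. A change in the use of their transcripts stays open, as the deposited values are per gene.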
